A study of Mus musculus with 10 samples.

How the data were processed

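Small RNA was sequenced from the RPE/choroid/sclera, the layers behind the neural retina (retinal pigment epithelium, vascular choroid and fibrous sclera), of wild-type C57BL/6J mice at postnatal day 34. Per the labels' protocols, a goggle with a -20 dioptre lens was worn over one eye for 10 days from postnatal day 24, and the other eye of the animal had no lens. Such a lens moves the image behind the retina, and eyes of young animals answer with growth toward myopia. The labels give the side of each eye and a number in the title shared by a left and a right library, but not which eye wore the lens. The 10 libraries were therefore grouped as 5 left and 5 right eyes, numbers 61, 64, 65, 66 and 68, and no library is called treated or control here. The extract protocol in the labels speaks of retinae, while the tissue label names the RPE/choroid/sclera, and the tissue label was followed. Libraries were made with the TruSeq small RNA kit from the small RNA fraction, per the labels' protocols.

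The authors' processing used Bowtie and Partek with the mouse build GRCm38 (mm10), per the submitters' processing notes, which give no versions. The deposited table holds a normalised signal for 1340 mature miRNAs in the 10 libraries. The sums of the deposited signal lie between 11878152 and 11879036 in the 10 libraries. Of the 134 highest ranks, 132 hold 10 values that span less than 1 percent of their mean, while this holds for 278 of the 1105 ranks above 0 in any library (25.2%). At the high ranks this is the form quantile normalisation leaves, and lower ranks are less alike, although the method is not given in the sources used here. Only 7.31% of the deposited signal values above 0 are whole numbers within 0.001, so reads could not be recovered, count models were not used and the depth of each library is unknown. No counting interval or detection floor is given for that reason. In such values an abundant miRNA takes the step of the rank it reaches, and a miRNA that ranks first everywhere has one value in all libraries.

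Values were analysed as log2(signal + 1), with the 588 miRNAs whose mean over the 10 libraries was at least 10. These hold 99.988% of the summed signal. Fold changes are on that scale, which understates the change of miRNAs with low signal. Right eyes were compared with left eyes by limma 3.58.1 in R 4.3.3, with a mean-variance trend, the shared number as a block, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The block follows the protocol, which compares each treated eye with the contralateral eye, and the pairing is taken from the shared title number. As a check on that pairing, the deviations of same-numbered eyes from their side means were correlated across miRNAs. The values were 0.12, 0.45, 0.01, -0.13 and 0.28 for the 5 numbers. Only 2 of the 5 left eyes were most like the right eye of their own number. The exact one-sided permutation of the pairing gave p = 0.158, so this check does not establish the pairing. Nothing in the labels tells whether the libraries of one number share a litter, a sequencing run or a day.

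The 20 lists of miRNAs, the tests, the other settings to be tried and the rule for named miRNAs were fixed before the data were examined. Lists with at least 3 members kept were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The summed signal of each of the 8 cell type lists was compared by an exact sign-flip permutation of the 5 pairs, in which the smallest two-sided p is 2 of the 32 sign patterns. Summed and high signals are given in k, units of 1000 signal. Likeness of same-numbered eyes was tested by an exact one-sided permutation over all 120 pairings of left with right eyes. The log2 ratio of the 5p to the 3p arm was compared by limma for the 158 hairpins with both arms kept. The rule for named miRNAs took those past the adjusted threshold first. Where these were fewer than 20, it filled up to 10 in each direction with the smallest unadjusted p among miRNAs with one direction in all 5 pairs, given as values and not as calls. It added the 10 most abundant miRNAs and the 2 most abundant members of each list. Names outside this rule are members of a list under discussion or are said to have been chosen after their values were seen.

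The comparison was tested on simulated data built from these 588 miRNAs, with 200 changed in each of 20 runs. At 1.5-fold 64.0% of the changed miRNAs were called, at 2-fold 85.8%, at 4-fold 99.0% and at 8-fold 100%, while 1.33% of the unchanged ones were called. Residuals were drawn independently for each miRNA. With 200 of 588 changed the adjusted threshold is milder than with few changed, so these shares overstate what would be called if only a few miRNAs differed. Rank steps can hold an abundant miRNA in place in the deposited values, as for miR-204-5p, with an SD of 0 over 10 libraries. A change in such a miRNA may not appear at all. For abundant miRNAs the shares can therefore overstate what would be called for that reason too. Coordinates are those of the deposited table on GRCm38, written with the end base included. With that reading, 8 of 8 known mature sequences compared were recovered exactly from the genome, and 1312 of the 1340 miRNAs lay inside a miRNA gene on the same strand in GENCODE release M21. Where a mature miRNA is made from several loci, the table gives 1 of them. Of the miRNAs, 41 had a row identical to that of another, so reads shared between near-identical copies cannot be assigned. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Alternatives were another pseudocount, filter, scaling, variance model, threshold or pairing, each number left out in turn, and settings added after seeing the data.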

Results

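Small RNA sequencing of the RPE/choroid/sclera gave a normalised signal for 1340 mature miRNAs in 10 libraries, 5 from left and 5 from right eyes that share the numbers 61, 64, 65, 66 and 68. In every animal one eye had worn a -20 dioptre lens for 10 days. The labels do not state which eye that was, so the contrast available is right against left eye. A lens effect that fell on different sides in different animals would be diluted or lost in that contrast. Of the 1340 miRNAs, 761 had a signal above 0 in all 10 libraries, and between 235 and 307 were listed at 0 in a library.

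The tissue was led by miR-204-5p, which is known for its high level in the pigment epithelium and is encoded in an intron of Trpm3 (chromosome 19, 22750610 to 22750631, plus strand). It ranked first in all 10 libraries with the same normalised signal of 1931810, 16.3% of the total, so its differences between libraries cannot be seen in these values. Next came miR-22-3p at 1013 ± 148 k (SD, n = 10, k for 1000 units of signal), let-7a-5p at 942 ± 196 k, miR-26a-5p at 899 ± 62.4 k and miR-181a-5p at 803 ± 73.7 k. The smooth muscle and fibroblast miRNA miR-143-3p (chromosome 18, 61649199 to 61649219, minus strand, outside any annotated host gene) stood at 794 ± 78.5 k. For miR-27b-3p, at 606 ± 71.1 k, the whole spread came from right eye 68 with 404 k, as the other 9 libraries all had 628 k. The photoreceptor miRNA miR-182-5p (chromosome 6, 30165962 to 30165986, minus strand) stood at 341 ± 292 k, a spread and a place in this order that rest on right eye 68. The other 9 libraries gave 251 ± 73.2 k, below the 326 k of miR-127-3p and 287 k of miR-30a-5p in the same 9. The imprinted miR-127-3p reached 318 ± 51.2 k and miR-30a-5p 289 ± 72.6 k. These 10 miRNAs held between 65.7% and 67.6% of the signal of each library.

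**Figure D1:**
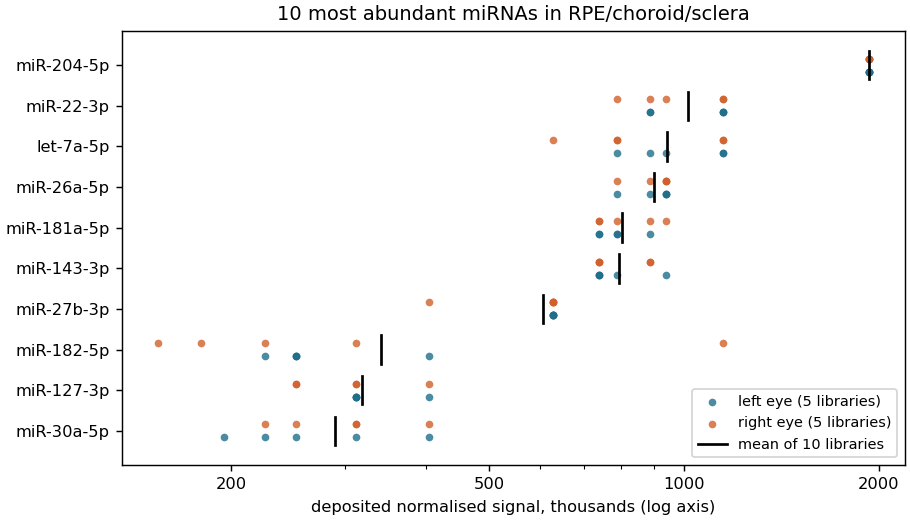
Normalised signal in k on a log axis for the 10 most abundant miRNAs, with each dot 1 library (blue left eye, orange right eye, overlapping dots drawn on top of each other) and the black bar the mean of 10 libraries. miR-204-5p has 1 value in all libraries, and miR-182-5p runs from 154 to 1150 k.

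The first comparison asked which single miRNAs differ between right and left eyes. None of the 588 miRNAs tested passed an adjusted p of 0.05 in limma, 13 had an unadjusted p under 0.05, of which 10 were higher and 3 lower in the right eye, and 29.4 would be expected by chance. The miRNAs with one direction in all 5 pairs numbered 17, 12 higher and 5 lower in the right eye. This is 2.89% of those tested, where chance gives 6.25% if no pair is tied. Pairs tied on a rank step, as all 5 are for miR-204-5p, lower that chance share. All miRNAs also share the same 5 pairs, so the shortfall is not read as a result. Among them was miR-29c-5p, the 5p arm of the miR-29c hairpin (chromosome 1, 195037562 to 195037583, plus strand, in an exon of the transcript A330023F24Rik). It had a signal of 29.8 ± 6.87 in left and 40.8 ± 4.51 in right eyes (SD, n = 5 each), a log2 fold change of 0.46 with adjusted p = 0.967 in limma. The opposite direction was seen for miR-30e-3p, from an intron of Nfyc (chromosome 4, 120772618 to 120772639, minus strand), at 532 ± 83.6 in left and 437 ± 155 in right eyes, a log2 fold change of -0.35.

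The other named miRNAs with a higher value in all 5 right eyes had low signals apart from miR-25-3p and miR-142a-3p. The log2 fold changes were 0.53 for miR-7226-3p, 0.51 for miR-16-2-3p, 0.37 for miR-877-3p, 0.66 for miR-3105-3p, 0.27 for miR-1191a, 0.22 for miR-150-3p and 0.33 for miR-1193-5p. For miR-25-3p, of the cluster in Mcm7, the signal was 11183 ± 1621.9 in left and 12646 ± 1486 in right eyes. The leukocyte miRNA miR-142a-3p had 248 ± 19.7 in left and 283 ± 28.2 in right eyes. Lower values in all 5 right eyes were also found for miR-669c-5p of the Sfmbt2 intron (log2 fold change -0.32), miR-6899-3p (-0.47), and the Dlk1-Dio3 miRNAs miR-485-3p (-0.25) and miR-494-3p (-0.20). The adjusted p of each of these was 0.967 in limma. For 497 of the 588 miRNAs (84.5%) the 95% interval excluded a 2-fold difference in either direction, and the median half-width of the interval was 1.297-fold. Rank steps can hold an abundant miRNA in place, as with the single value of miR-204-5p. For such miRNAs an excluded difference can come from the normalisation.

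**Figure D2:**
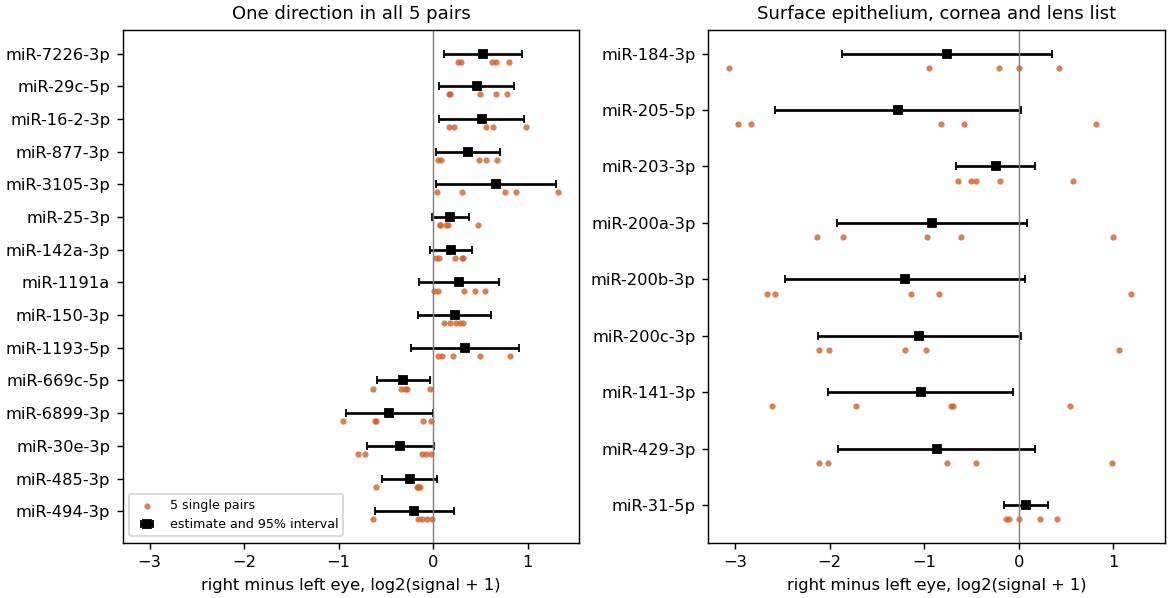
Right minus left difference in log2(signal + 1) for the 15 named miRNAs with one direction in all 5 pairs (left panel) and for the 9 members of the surface epithelium, cornea and lens list (right panel). Squares are limma estimates with 95% intervals and dots the 5 single pairs, and miR-205-5p has the lowest estimate at -1.28.

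Among the 20 lists, the surface epithelium, cornea and lens list had 8 of 9 members with a lower mean in right eyes and a median log2 fold change of -0.92, and none of the members passed the test. As a list it passed in camera with the preset correlation (adjusted p = 0.000104) and was lost at adjusted p = 0.897 with an estimated correlation. The largest difference was in miR-205-5p, a miRNA of stratified epithelia (chromosome 1, 193507503 to 193507524, minus strand, in an exon of 4631405K08Rik), with 11590 ± 4284 in left and 5544 ± 3594 in right eyes. The miR-200 group of epithelial cells had log2 fold changes of -1.21 for miR-200b-3p, -1.05 for miR-200c-3p, -1.04 for miR-141-3p, -0.92 for miR-200a-3p and -0.87 for miR-429-3p. For miR-184-3p, abundant in cornea and lens (chromosome 9, 89802263 to 89802284, minus strand), the signal was 140470 ± 66858 in left and 96398 ± 70379 in right eyes, with a log2 fold change of -0.76 that fell to -0.18 without number 66. The remaining members were miR-203-3p at -0.24 and miR-31-5p at 0.08, the latter -0.003 without number 65. The median of the list ran from -0.65 without number 66 to -1.39 without number 61.

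This was the 1 list of 19 tested to pass with the preset correlation. No list passed with an estimated correlation, which was 0.74 for this list, or in fry, which gave it adjusted p = 0.973. No member passed in limma, either over all miRNAs or adjusted over the list alone, where the lowest adjusted p was 0.124. Number 61 went the other way, with a summed list of 120 k in the left and 165 k in the right eye.

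The miR-29 family list holds 3p arms, which target collagen mRNAs, and also 5p arms. It had 5 of 6 members higher in the right eye with a median log2 fold change of 0.14, and did not pass in camera (adjusted p = 0.0881). Its most abundant members were miR-29a-3p, at 17755 ± 4685 in left and 19096 ± 4679 in right eyes, and miR-29c-3p, at 6155 ± 2634 and 6645 ± 2671. With the preset correlation, without number 64 this list passed at adjusted p = 0.0300 in camera, without number 66 the striated muscle list passed as lower in the right eye at 0.00430, and without number 68 the retina and neuron list passed as lower at 0.00235. With an estimated correlation none of these 3 held, at adjusted p = 0.767, 0.889 and 0.968 in the same order, and no list passed with any single number left out.

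Of the growth-related and ubiquitous families, the let-7 and miR-98 family had 6 of 9 members lower in the right eye (median log2 fold change -0.10, camera adjusted p = 0.346), with let-7c-5p at -0.21. The miR-30 family had 4 of 5 members higher (0.12, adjusted p = 0.346), with miR-30d-5p at -0.02. The miR-17 to miR-92 clusters, which include miR-92a-3p, had 6 of 13 higher (-0.01, adjusted p = 0.868). The miR-15 and miR-16 family, led by miR-16-5p and miR-497a-5p, had 4 of 6 higher (0.02, adjusted p = 0.948), and the miR-181 family, with miR-181b-5p, 3 of 4 higher (0.03, adjusted p = 0.948). The p53-linked miR-34 and miR-449 family, led by miR-34c-5p and miR-34a-5p, had 4 of 6 lower (-0.07, adjusted p = 0.447). The miR-10, miR-99, miR-100 and miR-125 group, with miR-125b-5p and miR-125a-5p, had 5 of 7 lower (-0.03, adjusted p = 0.346).

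The list of fibrosis, TGF-beta and hypoxia responsive miRNAs, led by miR-21a-5p and miR-192-5p, had 8 of 11 members higher (median 0.08, camera adjusted p = 0.710). The imprinted Dlk1-Dio3 cluster had 32 of 52 higher (0.03, adjusted p = 0.948), with miR-411-5p at 0.03, and the Sfmbt2 intronic cluster 6 of 11 lower (-0.19, adjusted p = 0.346), with miR-467d-5p at 0.02. Of 11 miRNAs named in earlier myopia work, which include let-7a-5p and miR-184-3p, 6 were lower (median 0.00 to 2 decimals, mean -0.09, adjusted p = 0.628). No member of any list passed in limma, adjusted over the list alone or over all 588 miRNAs.

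The next comparison asked whether the cell type makeup of the dissected tissue, read from summed marker miRNAs, differed between sides. Retina and neuron miRNAs summed to 324 ± 85.7 k in left and 475 ± 486 k in right eyes (SD, n = 5 each), and the right eye of number 68 alone held 1335 k, where the other 9 libraries held 192 to 476 k. Without number 68 the direction turned, with 339 k in left and 260 k in right eyes. In right eye 68 miR-182-5p had 1149510 and ranked second, and miR-183-5p of the same cluster had its highest value, 125511. Surface epithelium miRNAs summed to 165 ± 71.8 k in left and 113 ± 74.3 k in right eyes, lower in 4 of 5 right eyes, with 32.9 k in right eye 66 against 210 k in its left partner. Number 66 carried most of that difference, since without it the means were 153 and 133 k. Striated muscle miRNAs, of which miR-133a-3p and miR-133b-3p are the most abundant, gave 61.9 ± 30.7 and 53.6 ± 14.4 k. The erythroid list gave 87.6 ± 18.8 and 83.1 ± 25.4 k, almost all of it miR-486a-5p and miR-486b-5p (means of 41.3 and 41.7 k over the 10 libraries). These 2 have the same mature sequence on opposite strands of one site, so their reads cannot be told apart and may be counted more than once. Most of the retina and neuron sum was miR-182-5p (mean 341 k), and most of the surface epithelium sum was miR-184-3p (118 k).

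Leukocyte miRNAs, led by miR-146a-5p and miR-150-5p, summed to 20.4 ± 1.92 k in left and 21.03 ± 2.04 k in right eyes. Endothelial miRNAs, miR-126a-5p and miR-126a-3p from Egfl7, gave 228 ± 26.9 and 254 ± 54.9 k. Fibroblast and smooth muscle miRNAs, with miR-143-3p and miR-199a-3p, gave 923 ± 95.8 and 936 ± 92.8 k. RPE and melanocyte miRNAs gave 1979 ± 8.12 and 1976 ± 12.1 k, almost all of it the fixed value of miR-204-5p, while miR-211-5p of the Trpm1 intron had 45690 ± 7975 and 42776 ± 11906. With a single number left out the difference in mean turned direction in 6 of the 8 sums. Besides retina and neuron these were striated muscle (51.3 in left and 54.3 k in right eyes without number 68), erythroid (90.1 and 90.9 k without 68, 83.4 and 83.9 k without 64), and leukocyte (20.8 and 20.3 k without 66). The others were fibroblast and smooth muscle (936 and 911 k without 65, 923 and 910 k without 66) and RPE and melanocyte (1978.8 and 1979.8 k without 61). The endothelial means met at 232 k on both sides without number 66. None of the 8 sums differed between sides by the exact sign-flip permutation (lowest exact p = 0.3125 for the surface epithelium list, all adjusted p = 0.9375), and with 5 pairs the smallest possible p is 2 of 32 sign patterns, above the threshold. As lists in camera, RPE and melanocyte, retina and neuron, erythroid, leukocyte, and fibroblast and smooth muscle all had adjusted p = 0.948, and striated muscle 0.992. The endothelium list had 2 kept members and was not tested.

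**Figure D3:**
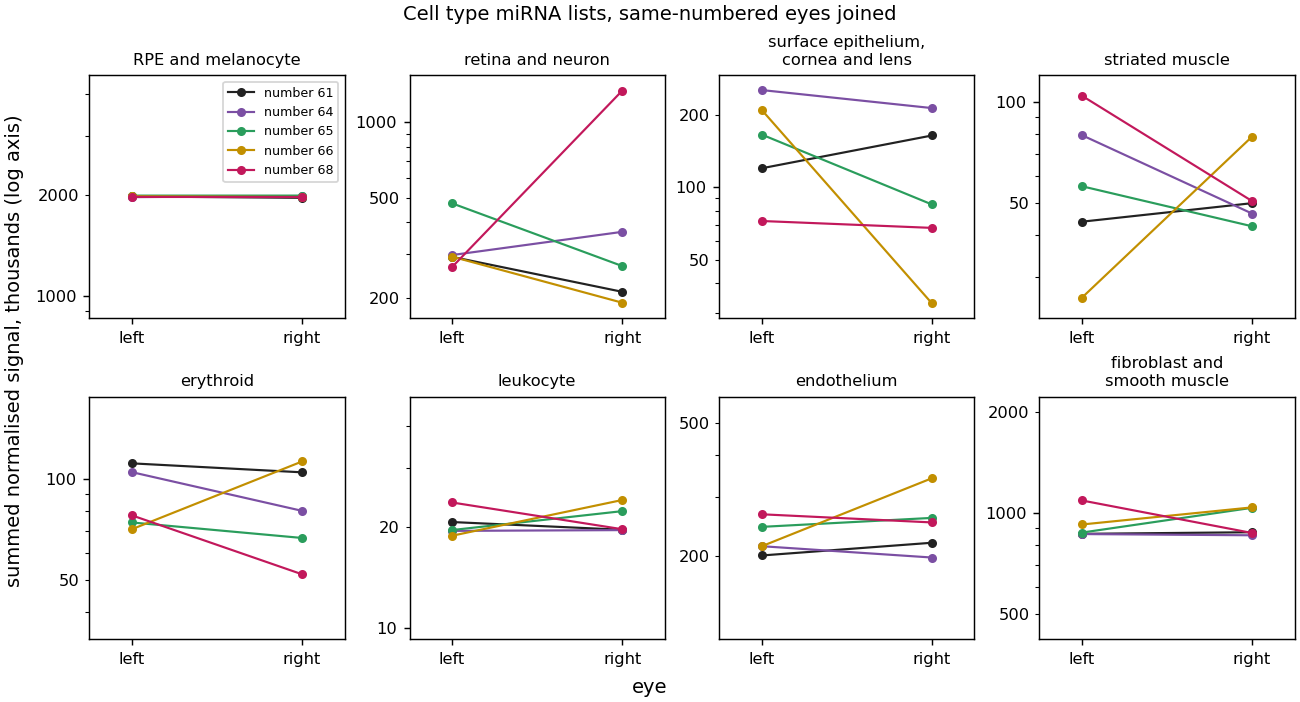
Summed normalised signal in k (log axis) of the 8 cell type lists in left and right eyes, with a line joining the eyes that share a number. Right eye 68 stands at 1335 k for the retina and neuron list, and 4 of 5 lines of the surface epithelium list go down to the right.

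Whether the eyes of one number resemble each other was asked from the deviations of each library from its side mean. The mean correlation across miRNAs was 0.146 for same-numbered eyes and -0.037 for eyes of different numbers, and 19 of the 120 pairings were as high (exact one-sided permutation p = 0.158). Centring on the side means ties the value for different numbers to that for same numbers, so it is no separate comparison. With Spearman correlation the mean was 0.263 (exact permutation p = 0.025), and without a filter on low signal it was 0.0763 (exact permutation p = 0.0417). Only 2 of the 5 left eyes were most like the right eye of their own number. The signal levels of any 2 libraries correlated at 0.972 to 0.993 across miRNAs, which are not independent replicates.

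The let-7, miR-29 and miR-30 families varied between numbers. The let-7 and miR-98 family summed to 1975 and 1994 k in the left and right eye of number 61 and to 1962 and 1975 k in number 64. It summed to 1533 and 1381 k in number 65, 1500 and 1395 k in number 66, and 1338 and 1113 k in number 68. Part of the low sum in right eye 68 can be a rank step, since miR-182-5p ranked above let-7a-5p there. The miR-29 family had 17.4 and 20.5 k in number 61, 20.2 and 17.7 in number 64, 25.7 and 29.7 in number 65, 22.5 and 29.4 in number 66, and 36.3 and 34.2 in number 68. The miR-30 family had 414 and 428 k in number 61, 393 and 422 in number 64, 499 and 669 in number 65, 540 and 568 in number 66, and 682 and 603 in number 68. The means of the numbers spanned 759 k for let-7, 16.3 k for miR-29 and 235 k for miR-30, where the largest gap between the eyes of a number was 225, 6.89 and 170 k. These families were singled out after their values were seen, and no test was made of the difference between numbers.

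**Figure D4:**
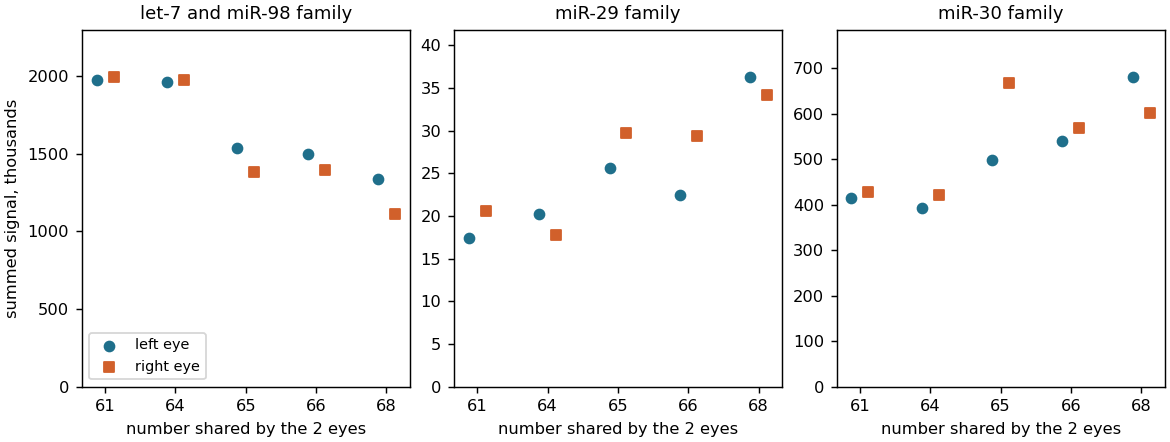
Summed normalised signal in k of the let-7 and miR-98, miR-29 and miR-30 families for each number, with circles for left and squares for right eyes. The let-7 sums run from 1113 k in right eye 68 to 1994 k in right eye 61.

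The last comparison asked whether the arm of the hairpin that is kept differs between sides. None of the 158 hairpins passed in limma (lowest adjusted p = 0.792), and 3 had an unadjusted p under 0.05. The ratios are of normalised signals and not of reads, so rank steps enter them. For miR-204 the 5p signal is fixed, and the ratio varies only with the 3p arm. The 5p arm was the higher one in 90 hairpins and the 3p arm in 68, and in 36 the arms differed over 100-fold. The largest difference was in miR-377 of the Dlk1-Dio3 cluster, where the log2 ratio of 5p to 3p was 0.70 in left and -0.13 in right eyes. Without number 61 it was the 1 hairpin that passed (adjusted p = 0.0299 in limma, a difference of -1.14), and it was chosen here after its values were seen.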

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

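The counts over other splits of the libraries for miRNAs and lists and the tests on the epithelial and retinal miRNAs were chosen after the results were seen, while the count over splits for the arms and both tests on the first principal component were planned before theirs.

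In 16 of 145 checks over lists and named miRNAs, 1 eye lay far from the other 4 of its side on the log2 scale. Chance gives about 1 in 20 for independent, normally distributed values. Here sums were checked beside their own leading members and some values are tied rank steps, so the count cannot be set against that rate. Left eye 68 was apart in miR-143-3p (939897), miR-92a-3p (31564), miR-16-5p (79250), miR-181b-5p (60162) and the fibroblast and smooth muscle sum (1089 k). Left eye 66 was apart in miR-127-3p (403594) and the Dlk1-Dio3 sum (523.5 k), and left eye 65 in miR-182-5p (403594) and the retina and neuron sum (476 k). Right eye 66 was apart in the striated muscle sum (78.8 k), miR-133a-3p (71843), miR-133b-3p (5093) and miR-125b-5p (179294). The others were miR-125b-5p in left eye 61 (179294), miR-27b-3p in right eye 68 (403594) and miR-1191a in left eye 64 (14.5). On the untransformed scale, added after seeing the data, there were 19. Right eye 68 then joined with the retina and neuron sum (1335 k), miR-182-5p and miR-183-5p, and right eye 66 with miR-126a-3p, while miR-1191a dropped out. Several of these values are neighbouring rank steps of the normalised signal.

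The surface epithelium, cornea and lens list passed as lower in right eyes only in camera with the preset correlation, and was lost with an estimated correlation (adjusted p = 0.897). Chance cannot be excluded, since 3 of the 16 ways to orient the 5 pairs gave a camera p as small, and the sum was lower in 4 of 5 right eyes, which leaves eye side open. Over all 6 loci of the list the right minus left differences had a median correlation of 0.805 over 5 pairs (range -0.03 to 0.989). Without miR-31-5p, left out because it did not move with the others (-0.03 to 0.356), it was 0.902, a rise set by that choice. The median over all 6 loci could come from differing amounts of corneal, conjunctival or lens tissue left on the dissected eyecup. No test here tells such carry-over from regulation shared by the loci, and a lens effect could not be tested without knowing the treated eye.

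The retina and neuron list was high in right eye 68, where 12 of 14 kept members had their highest value. Retinal tissue carried into that library may account for it. A retina library under a wrong label is argued against by the fibroblast, muscle and endothelium sums, 3 of 3 inside the range of the other 9 libraries. Eye side is argued against by the list being higher in the right eye in 2 of 5 pairs.

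The first principal component, on which let-7 lies opposite to miR-29 and miR-30, held 31.1% of the variance between libraries. After the GC trend of each library was removed it held 29.3%, which argues against a linear GC trend as the whole cause. The weights of the miRNAs on the component still went with GC content, at r = 0.333 across 586 miRNAs. The slope of signal on GC was 0.0544 log2 per 10 GC points in right eye 61, which had the highest score. It was -0.135 in right eye 68, which had the lowest. Base composition can therefore be a part of the pattern. Without the 60 members of the cell type lists it held 32.1%. The threshold set beforehand would have read this as evidence against retinal and epithelial tissue, but 60 of 588 miRNAs leave most miRNAs of those tissues in place, so other tissue could still contribute and the reading was withdrawn after the value was seen. Differences between animals and unrecorded batches stay open and untested.

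Among the 16 orientations that part all 5 pairs as the real split does, 13 gave at least 1 list, 8 gave more lists than the real one (highest other 7), and 12 had at least its 13 miRNAs at an unadjusted p under 0.05 (highest other 92), so chance cannot be excluded for these counts. Of 100 splits of the 10 libraries drawn from 126, with the real one included, 78 had at least 13 at an unadjusted p under 0.05 (highest other 94) and 84 at least 1 list (highest other 7). With the number as a block, a split rests on the pairs it parts, so these 100 hold 55 distinct comparisons. Of the 100, 24 part 1 pair, 65 part 3 and 11 part all 5, and the 94 comes from one that parts 3. For miRNAs and arms past the adjusted threshold the real count is 0, which all 100 reach by definition (highest others 7 and 1), so the splits say nothing about those counts.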

How the results depend on the processing

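The settings that leave out right eye 68, remove the GC trend or join an estimated correlation with left-out libraries were chosen after seeing the data. The count of 0 miRNAs in limma held in all 18 alternatives, with a lowest adjusted p of 0.335 and between 5 and 49 at an unadjusted p under 0.05. Without the replicate block it was 0 as well, with 12 at an unadjusted p under 0.05, and dropping the pairing changed no other call. The count of lists past the threshold went from 1 to 0 with an estimated correlation, where the surface epithelium list had adjusted p = 0.897 (from 3.56e-10 to 0.0272 over the alternatives with the preset correlation). With an estimated correlation the count was also 0 without number 61, 64, 65, 66 or 68, where that list had adjusted p = 0.9999, 0.767, 0.923, 0.889 and 0.968, and with no block and right eye 68 left out (0.645). With the preset correlation it was 2 with no block and right eye 68 left out, where the retina and neuron list also passed as lower in right eyes (adjusted p = 0.00139), and 1 to 2 with single numbers left out. Same-numbered eyes passed with Spearman correlation (0.263) and with no filter (0.0763). The arm count was 0 to 1 with single numbers left out. The estimated correlation of the epithelial members, 0.74, accounts for that loss, and the cause of the others was not tested. Of 907 alternative values of 54 named miRNAs, 903 moved by less than the SD of the 5 pair differences and 54 had the opposite sign. Leaving out 1 of 5 pairs cannot move a mean by that SD, and dropping the block leaves the fold change as it is. The count of 903 was therefore largely set beforehand and is no sign of stability. None of the opposite signs were among the 15 with one direction in all pairs, which were chosen for it, so no left-out pair could turn them. Other scalings moved the median difference by little, from 0.02 as deposited to 0.00 at the lowest. The planned count models were not run, since reads could not be recovered, and the unknown depth leaves the precision of low signals open.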

Other observations

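Values in this part were chosen after they were seen, and no test was made of them. In left eye 66, miR-219a-2-3p, a miRNA of oligodendrocytes, had a signal of 501, where the other 9 libraries had 28.01 to 57.5. Its partner arm miR-219a-5p stayed between 11.1 and 29.9 in all 10 libraries. The muscle miRNA miR-1a-3p lay between 229 and 1929, while miR-133a-3p, made from the same clusters, lay between 23998 and 93999. The red cell miRNA miR-451a lay between 860 and 1982, while miR-486b-5p lay between 25150 and 57345.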
